A study of Homo sapiens with 24 samples.

How the data were processed

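Total RNA was measured by sequencing in 12 papillary thyroid carcinomas and 12 matched noncancerous tissues. Per the labels' protocols, samples with an RNA integrity number above 4 entered a strand-specific total RNA library kit that removes ribosomal and mitochondrial RNA, and were sequenced from both ends. The authors used FastQC, Bowtie2, TopHat and Cufflinks on hg19, per the submitters' processing notes; their versions, the annotation release, filters and whether quantification used strand are not given in the sources used here. Expression was deposited as FPKM by the authors in a GENCODE table of 57798 genes and in a UCSC-named table of 53492 assembled loci, 26084 of them without a gene symbol. No further scaling is stated. Positions in the GENCODE table are those of the locus of overlapping genes, and are given here, as a locus, for AC079630.2 and RP11-1022B3.1. Other gene positions come from reference transcripts of the deposited assembly on hg19.

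Gene classes came from GENCODE release 29, matched by identifier for 52326 genes and not for 5472. That release is on another build, so none of its coordinates were used. It marked 13084 genes as lncRNAs. Y-linked genes and XIST were left out throughout, and immunoglobulin and T cell receptor segments were not named.

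A listed 0 in the UCSC-named table is not always a low value. Among 16185 protein-coding genes in both tables, 6 were at 0 in at least 1 library where the other table held 5 FPKM or more. DDX39B was at 0 in all 24 libraries, and TG in 14, 11 noncancerous and 3 tumour. This comparison kept the 1141 loci on alternative haplotype sequences, so the row of DDX39B may be such a copy, which was not checked. TG in the GENCODE table was at least 9251 FPKM in those 14 libraries and at most 4598 in the others. Values of TG in the UCSC-named table were therefore not used for any statement on its level.

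FPKM values were transformed to log2(FPKM + 0.1), and genes with a mean FPKM of at least 0.5 over all libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend). The fit had case as a block, and p-values were two-sided and adjusted by the Benjamini-Hochberg method at 0.05. Pairing comes from the design text and the case numbers in the titles, which mark tissue of the same donor. Deviations of same-case libraries from their group means correlated at 0.0194 to 0.482, with a median of 0.134 against -0.0117 for other pairs of libraries. Without the replicate block 4982 GENCODE genes changed, against 5526 with it. Single values per library were compared by exact permutation over all 4096 swaps within pairs. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

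The lists were fixed before the data were examined, from general knowledge. They covered thyroid hormone synthesis and differentiation, papillary thyroid carcinoma markers of earlier studies, MAPK output, immediate early genes, extracellular matrix, cell junctions, proliferation, interferon response, class II antigen presentation, metallothioneins, fatty acid and mitochondrial oxidation, known lncRNAs, histones and mitochondrial mRNAs. Others held markers of T and NK, B and plasma, myeloid, mast, endothelial, fibroblast, smooth muscle, skeletal muscle, adipocyte, parathyroid and C cells and red cell genes. Unless said otherwise, counts of list members below are of those past the FPKM filter.

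Named genes followed a rule fixed at the same time. It took the 10 largest rises and 10 largest falls past the threshold with a mean FPKM of at least 1 and the same sign in at least 11 of 12 pairs, then 6 and 6 lncRNA genes and 3 and 3 loci without a symbol with a mean FPKM of at least 0.5. From each list it took up to 4 members with the smallest p in the direction most members took, up to 2 in the other, and the member with the highest mean. TG, PAX8, XLOC_051122 and XLOC_006074 were included whatever their values, and results for some genes the rule takes are left out of the text. TSHR, FOXE1, HHEX, SFTPB, S100A4, COL1A1, COL3A1, FAP, SLA and DDX39B were named after their values were seen.

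On simulated FPKM with 200 changed genes, limma recovered 55 of 100 2-fold and 88 of 100 4-fold changes in the GENCODE table, with 3 calls among 19247 unchanged genes, and 47 and 90 of 100 in the UCSC-named table, with 6 calls among 25978. The simulated noise was independent between genes and used the variances limma had estimated. Far fewer genes were changed than were called in the real libraries. These rates need not hold for the real libraries. Absolute depth is unknown, so no counting intervals are given. Relative depth was estimated from the commonest ratio of low values between libraries in 6147 genes, and checked on simulated depths. Alternatives were the fit without the block, pseudocounts of 1 and 0.01, no filter or a mean FPKM of at least 2, median-ratio, quantile and sum scaling, array weights, an exact signed-rank test, a test against a 1.5-fold change, the other table and each pair left out. Clinical parameters named in the design text are not in the labels and were not analysed here.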

Results

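RNA sequencing compared 12 papillary thyroid carcinomas, the most common cancer of thyroid follicular cells, with 12 matched noncancerous thyroid tissues. The study's stated purpose was to find long noncoding RNAs (lncRNAs) that differ between tumour and noncancerous tissue. Each library came from total RNA depleted of ribosomal RNA, and the deposited values were FPKM, fragment counts scaled to gene length and sequencing depth, on the hg19 genome build. Total read numbers are not in the tables analysed here. The spacing of the lowest values gave a relative depth between 0.627 and 1.24 of the average library, with 1.04 ± 0.136 in tumours and 0.976 ± 0.0978 in noncancerous tissues (SD, n = 12 each; exact two-sided permutation p = 0.207). The difference in depth was smaller than the spread between libraries. Each pair is from a separate donor, so the p-values of single genes and of values per library are across donors, while those of camera also rest on the number of genes in a list.

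The first question was how gene expression in tumours differed from that in the matched tissue. Of 27 genes of thyroid hormone synthesis and differentiation, 17 were lower and 2 higher in tumours, while 29 of 31 genes known from earlier studies of this cancer were higher. As lists, both passed camera with its preset correlation but not with an estimated one (adjusted p = 0.404 and 0.0881 with an estimated correlation). TFF3, a secreted trefoil peptide, fell from 625 ± 295 to 12.2 ± 17.4 FPKM (SD, n = 12). ZCCHC12, a zinc finger gene on the X chromosome, rose from 6.06 ± 13.3 to 382 ± 478 FPKM (SD, n = 12). Both moved in the same direction in 12 of 12 pairs. Of 19447 genes tested with limma, 5526 passed an adjusted p of 0.05, 2608 of them higher and 2918 lower in tumours. The larger side depended on the filter, with 2242 higher and 2092 lower among genes with a mean FPKM of at least 2. Among the 5526 genes, 937 were at least 2-fold higher and 1412 at least 2-fold lower on the log2(FPKM + 0.1) scale, which understates changes of low genes. That lean depended on the scale, with 1097 higher and 1138 lower after quantile normalization and 624 and 648 with a pseudocount of 1. Dividing each library by its summed FPKM left 2279 genes, of which 27.4% were higher against 47.2% as deposited, and shifted the median change of all genes to -0.18.

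The largest rises after ZCCHC12 belonged to genes with low values in noncancerous tissue, with means from 0.234 (SLC22A31) to 1.22 FPKM (PRR15). HMGA2, a chromatin protein of embryonic tissues (chromosome 12, 66218240 to 66360071), rose by a log2 fold change of 5.98 ± 0.41 (SE, limma adjusted p = 5.7e-07). SLC22A31, an organic ion transporter gene, rose by 6.17 ± 0.52 (adjusted p = 3.4e-06), and TRPC5, a cation channel gene, by 5.92 ± 0.33 (adjusted p = 9.3e-08). PRR15, RXRG, LIPH, GABRB2 and ARHGAP36 followed with log2 fold changes of 5.74, 5.37, 5.34, 5.33 and 5.19. The largest falls after TFF3 were those of CCL21, a chemokine of lymphatic vessels, with -6.24 ± 0.57 (adjusted p = 6.3e-06), and of SLC5A5, the iodide transporter, with -5.85 ± 0.54 (adjusted p = 6.5e-06). LRP1B, CDH16, DPT, ADH1B, ZMAT4 and SEMA3D had log2 fold changes of -5.20, -5.19, -5.09, -5.04, -4.87 and -4.84. The rule that chose these genes required the same sign in at least 11 of 12 pairs, so that agreement is not a separate result.

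**Figure D1:**
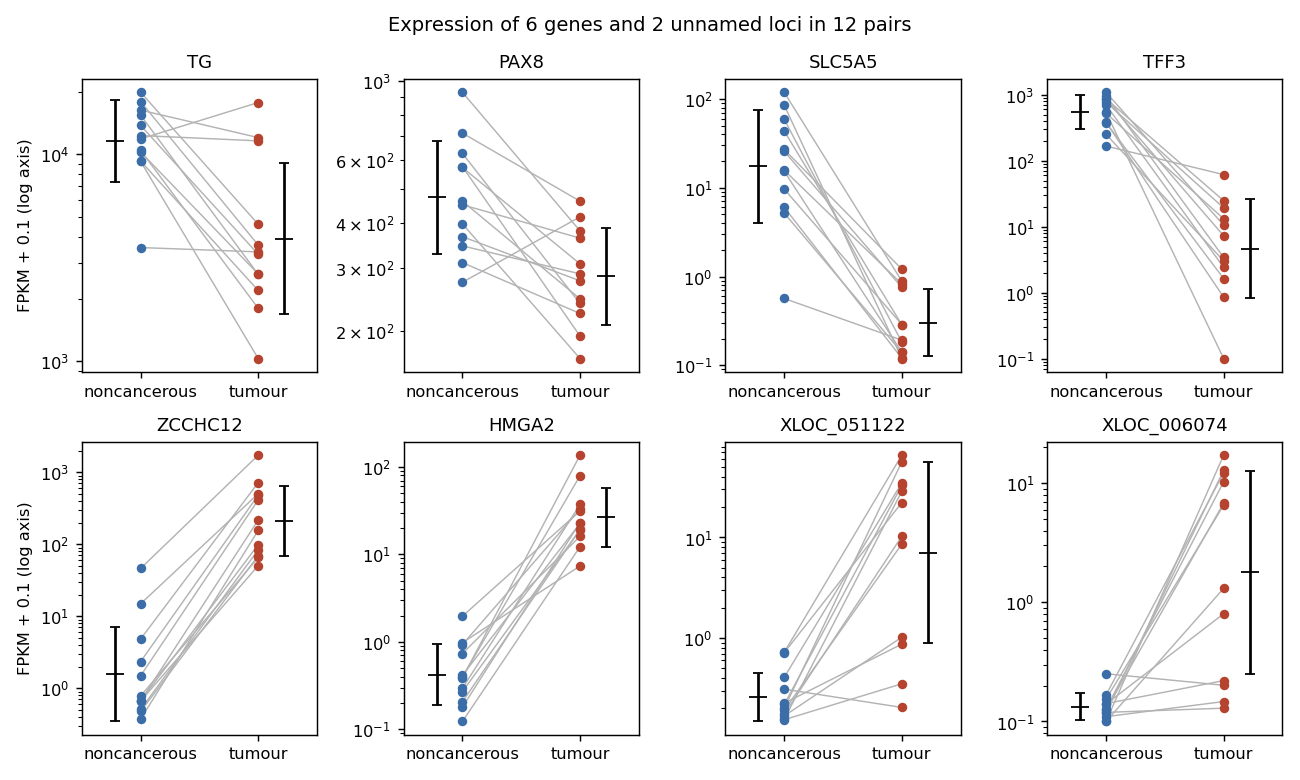
FPKM + 0.1 on a log axis in noncancerous and tumour libraries for 6 genes and 2 loci without a gene symbol. Points are libraries, grey lines join the 12 pairs, and black marks give the mean ± SD of the log2 values. TFF3 and SLC5A5 fell and ZCCHC12 and HMGA2 rose in 12 of 12 pairs.

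Of 27 thyroid hormone synthesis and differentiation genes, 17 fell and 2 rose, 17 and 4 when adjusted over the list alone (camera adjusted p = 2.3e-06). The list's call did not hold with an estimated correlation (adjusted p = 0.404 with an estimated correlation). Thyroglobulin (TG, chromosome 8, 133879205 to 134147143), the hormone precursor, fell from 12548 ± 4490 to 5557 ± 5273 FPKM (SD, n = 12; log2 fold change -1.57 ± 0.37 SE, limma adjusted p = 0.0056) and was lower in 11 of 12 pairs. The transcription factor PAX8 fell from 502 ± 190 to 297 ± 91.4 FPKM (SD, n = 12; log2 fold change -0.73 ± 0.17 SE, adjusted p = 0.0051). NKX2-1, a thyroid transcription factor, rose by 0.55 and DUOXA1, a maturation factor of the hydrogen peroxide enzyme, by 0.43. The receptor TSHR, FOXE1 and HHEX had log2 changes of -0.17, -0.42 and -0.11 that did not pass the threshold. TG made up 0.302 ± 0.248% of summed FPKM in tumours and 0.892 ± 0.481% in noncancerous tissue, lower in 12 of 12 pairs (exact permutation p = 0.00049, the smallest these pairs allow). Summed FPKM follows short RNAs, and of the sum over protein-coding genes alone TG made up 1.66 ± 1.58% and 3.99 ± 1.41% (SD, n = 12), lower in 11 of 12 pairs (exact permutation p = 0.0024).

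Of 31 papillary thyroid carcinoma markers of earlier studies, 29 rose and none fell, and 30 rose when adjusted over the list alone (camera adjusted p = 1.1e-28; adjusted p = 0.0881 with an estimated correlation). The members SFTPB and S100A4 did not pass the test. LRP4, a membrane receptor gene, rose from 3.57 ± 1.44 to 102 ± 70.4 FPKM, and fibronectin (FN1) from 75.1 ± 99.3 to 2305 ± 2376 FPKM (SD, n = 12 each). Of 22 genes driven by MAPK signalling, 15 rose and none fell, with 16 rising when adjusted over the list alone (camera adjusted p = 3.0e-07; adjusted p = 0.324 with an estimated correlation). They included the transcription factors ETV5 and ETV4, at log2 changes of 1.85 and 3.53, the cyclin CCND1 at 1.77 and the phosphatase DUSP6 at 2.26.

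Immediate early genes, which respond within minutes to growth signals and tissue handling, went the other way. Of 20, none rose and 14 fell, and 15 fell when adjusted over the list alone (camera adjusted p = 5.3e-07; adjusted p = 0.454 with an estimated correlation). FOS fell from 847 ± 288 to 246 ± 239 FPKM (SD, n = 12; adjusted p = 0.00093), and JUN, FOSB and CYR61 had log2 changes of -2.09, -3.78 and -2.01. All 8 metallothioneins tested fell, also when adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.296 with an estimated correlation), with MT1F at -2.96 and MT1X at -1.63. Members of this family and of the globins are near-identical, so reads may be split between them by the authors' quantification. Of 20 fatty acid and mitochondrial oxidation genes, 8 fell, 9 when adjusted over the list alone (camera adjusted p = 0.0086; adjusted p = 0.454 with an estimated correlation), among them PPARGC1A at -2.85.

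Genes of cell junctions and epithelial state moved both ways. Of 25, 12 rose and 4 fell, with 13 and 5 when adjusted over the list alone (camera adjusted p = 0.0089; adjusted p = 0.454 with an estimated correlation). The cadherin CDH3, the claudins CLDN16 and CLDN1 and the cadherin CDH2 rose by log2 changes of 4.06, 4.91, 4.28 and 3.22, while the kidney and thyroid cadherin CDH16 and the repressor ZEB1 fell. Of 28 extracellular matrix genes, 11 rose and 1 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.00078; adjusted p = 0.454 with an estimated correlation). COL13A1, LAMB3 and ITGA2 had log2 changes of 2.98, 3.96 and 2.70, and COL6A3 fell by 0.77. Of 20 proliferation genes, 5 rose, 7 when adjusted over the list alone (camera adjusted p = 0.00049; adjusted p = 0.454 with an estimated correlation), including TYMS at 2.40 and TOP2A at 1.41.

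Markers of several other cell types were lower in tumours. Of 18 T and NK cell markers, 12 fell, 13 when adjusted over the list alone (camera adjusted p = 2.9e-05; adjusted p = 0.404 with an estimated correlation), with CD3D at -1.55 and GZMK at -1.57. Of 14 fibroblast markers, 7 fell, 8 when adjusted over the list alone (camera adjusted p = 0.00049; adjusted p = 0.454 with an estimated correlation). DCN fell from 254 ± 128 to 39.3 ± 56.8 FPKM (SD, n = 12), while COL1A1, COL3A1 and FAP of the same list did not pass the threshold. Of 14 endothelial markers, 8 fell, 9 when adjusted over the list alone (camera adjusted p = 0.00078; adjusted p = 0.454 with an estimated correlation), with TIE1 at -0.98. Of 11 smooth muscle and pericyte markers, 5 fell, 6 when adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.481 with an estimated correlation), with LMOD1 at -2.77. All 3 red cell genes tested, of 7 listed, fell, also when adjusted over the list alone (camera adjusted p = 0.0016, and 0.324 with an estimated correlation). HBB fell from 325 ± 270 to 51.9 ± 36.6 FPKM (SD, n = 12). Of 15 skeletal muscle markers listed, 5 were tested, among them DES, which is also in the smooth muscle list. Of the 5, 4 fell and MYLPF rose, also when adjusted over the list alone (camera adjusted p = 0.0086, and 0.239 with an estimated correlation). Of 15 B and plasma cell markers, 3 fell and CD22 rose, with 2 and 1 when adjusted over the list alone (camera adjusted p = 0.040; adjusted p = 0.718 with an estimated correlation).

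The remaining lists did not pass camera. Of 17 myeloid markers none changed, also when adjusted over the list alone (median log2 change 0.40, adjusted p = 0.170), and of 5 mast cell markers only KIT fell (adjusted p = 0.420). Of 22 interferon response genes, 2 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.420), and of 12 class II antigen presentation genes CTSS rose (adjusted p = 0.594). The class II median was -0.04 while its mean was 0.06. Of 10 adipocyte markers, 2 rose and 2 fell, with 2 and 5 when adjusted over the list alone (adjusted p = 0.420), LPL at 1.87 and CFD at -2.59. Of 29 lncRNAs named in earlier cancer or thyroid studies, 5 rose and 8 fell, with 8 and 10 when adjusted over the list alone (adjusted p = 0.672), TNRC6C-AS1 at 2.50 and PTCSC3 falling from 31.0 ± 9.16 to 12.9 ± 9.03 FPKM (SD, n = 12). Of 12 replication-dependent histones, HIST1H1D rose and HIST1H4C fell (adjusted p = 0.369). None of 4 C cell markers (adjusted p = 0.439) or 13 mitochondrially encoded mRNAs (adjusted p = 0.351) passed, the latter after a kit that removes mitochondrial RNA. One of the 4 parathyroid markers, CHGA, was tested, at a log2 change of -1.24 (adjusted p = 0.199). In all, 16 of 25 lists passed camera with its preset correlation and none with an estimated one. All of the 16 but the B and plasma cell list also passed fry, with adjusted p-values of at most 0.028 (extracellular matrix). Fry asks whether the genes of a list change, and not whether they change more than other genes. An exact swap test of each list's mean against all genes, chosen after the data had been seen, passed 16 lists, 15 of which camera had called. The other was the adipocyte list, lower than all genes by a log2 difference of -0.65 ± 0.78 in 11 of 12 pairs (SD, n = 12; swap test adjusted p = 0.0044).

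**Figure D2:**
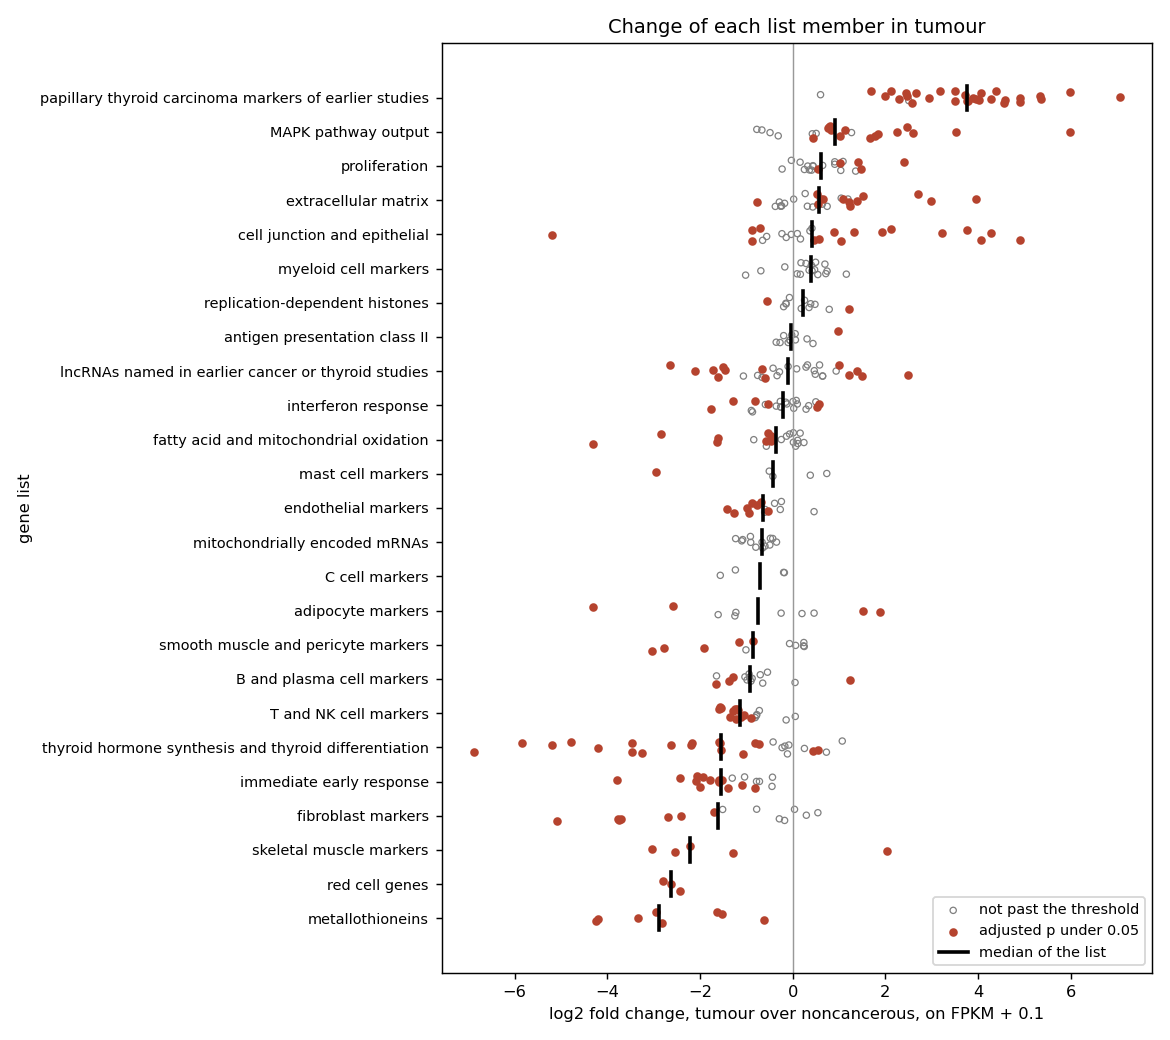
Log2 fold change of each tested member of 25 gene lists, tumour over noncancerous, on FPKM + 0.1. Filled points passed an adjusted p of 0.05, open points did not, and black bars mark list medians, from -2.89 for the metallothioneins to 3.76 for the papillary thyroid carcinoma markers.

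The second question concerned lncRNAs, the subject of the series. More lncRNA genes were lower than higher in tumours, and the single largest change was a rise. Of 2384 lncRNA genes tested, 602 changed, 177 higher and 425 lower, and 573 changed when adjusted over the lncRNA genes alone. Their median log2 change was -0.23, against 0.01 for 13980 protein-coding genes. The split depended on scaling: with quantile normalization 549 changed and 45.7% of them were higher, against 29.4% as deposited. Of changes of at least 2-fold, 107 were higher and 251 lower as deposited, 156 and 163 with quantile normalization and 51 and 62 with a pseudocount of 1. AC079630.2, at a locus on chromosome 12 (40550041 to 40561509) between SLC2A13 and LRRK2, rose from 0.290 ± 0.421 to 21.1 ± 13.7 FPKM (SD, n = 12; log2 fold change 6.13 ± 0.47 SE, limma adjusted p = 1.6e-06). RP11-280O1.2, RP11-476D10.1, RP11-230G5.2, AC007255.8 and RP11-474O21.5 rose by 4.93, 4.82, 4.69, 4.45 and 3.97. The loci of RP11-280O1.2, AC007255.8 and RP11-476D10.1 lie near RXRG, PRR15 and AC079630.2, which also rose, so these changes may not be separate. RP11-1022B3.1, at a locus on chromosome 12 (63686409 to 63753817), fell from 4.70 ± 2.81 to 0.101 ± 0.235 FPKM (SD, n = 12; adjusted p = 1.7e-06). RP11-456O19.4, AC078842.3, CTD-2008L17.2, RP5-1024C24.1 and RP11-807H7.2 had log2 changes of -3.79, -3.59, -3.50, -3.48 and -3.40. RP11-456O19.4 and CTD-2008L17.2 are listed at the same locus, so their falls may not be separate either.

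The third question used the authors' second table, in which transcripts assembled from the reads were joined with UCSC gene names. Of 26178 genes and loci tested, 8958 changed, 4232 higher and 4726 lower. Of these, 2978 belonged to 9383 intergenic loci without a gene symbol, 1044 higher and 1934 lower, and 8332 of those loci had a single exon. As deposited, 35.1% of the changed loci without a symbol were higher, against 49.1% with quantile normalization and 60.5% when a mean FPKM of at least 2 was required, where the share over all changed genes and loci was 58.5% against 47.2%. XLOC_011325 and XLOC_011324 rose from 0.0326 ± 0.113 to 11.2 ± 6.03 FPKM and from 0.167 ± 0.206 to 15.5 ± 8.04 FPKM (SD, n = 12). Both lie inside the locus of AC079630.2. XLOC_054510 (chromosome X, 124335826 to 124336078) was listed at 0 in every noncancerous library and averaged 7.82 ± 7.34 FPKM in tumours (SD, n = 12). XLOC_025829 (chromosome 2, 1553303 to 1554124) fell by 4.82 ± 0.55 on the log2 scale. XLOC_012930, over the locus of RP11-1022B3.1, and XLOC_042703 had log2 changes of -4.73 and -4.55.

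XLOC_051122 (chromosome 9, 109984409 to 110018228, 27289 bases from RAD23B) rose from 0.203 ± 0.207 to 21.8 ± 22.5 FPKM (SD, n = 12; log2 fold change 4.78 ± 0.72 SE, limma adjusted p = 0.00020). XLOC_006074 (chromosome 10, 54643922 to 54681370, 112462 bases from MBL2) rose from 0.0377 ± 0.0412 to 5.61 ± 6.11 FPKM (SD, n = 12; 3.75 ± 0.76 SE, adjusted p = 0.0018). Each was higher in 11 of 12 pairs, but the rise was uneven. XLOC_051122 was at 0.919, 0.251, 0.770 and 0.104 FPKM in tumours 4, 7, 8 and 11, and at 8.49 or more in the other tumours. XLOC_006074 was at 0.0294, 0.0471, 0.120 and 0.101 FPKM in tumours 7, 8, 10 and 11, and at 0.701 or more in the others. Both loci have up to 4 exons in the assembly. TG cannot be read from this table: it and SLA, which lies in the same interval, were listed at 0 in 14 libraries in which the other table held at least 9251 FPKM of TG.

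Tumours differed from one another more than noncancerous tissues did. The root mean square distance of a library to its group mean was 0.939 ± 0.131 in tumours and 0.807 ± 0.130 in noncancerous tissue on the log2 scale (SD, n = 12), larger in 11 of 12 pairs (exact permutation p = 0.0098). The distances were swapped without computing new group means, and those of a group share its mean, so this p is approximate. Tumours also had fewer genes at 1 FPKM or more, 15724 ± 365 against 16174 ± 315 (SD, n = 12; exact permutation p = 0.0024). The difference also passed at 0.1 FPKM or more (exact permutation p = 0.0015) but not after sum scaling (exact permutation p = 0.232). Short noncoding RNAs took between 61.4% and 97.8% of a library's summed FPKM. The 10 most abundant genes held 64.8 ± 13.2% and 64.3 ± 7.88% of summed FPKM (SD, n = 12), a difference smaller than the spread (exact permutation p = 0.863).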

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

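The exact swap test of the lists and the count without the TG interval (8956 loci) were chosen after the data had been seen; the other alternatives were fixed before. Leaving out each pair gave 4743 to 5629 changed GENCODE genes, 481 to 620 lncRNA genes, 7819 to 9213 genes and loci in the UCSC-named table and 15 to 17 lists. Without the replicate block the counts were 4982, 549, 7950 and 15, and dropping the pairing ended 1 list call, that of the B and plasma cell markers. Sum scaling gave 2279 genes and 340 lncRNA genes; short RNAs held a median of 74.5% of summed FPKM and up to 97.8%, so this sum follows them. It shifted the median of all genes to -0.18, and the loss of genes detected (-958.4) no longer passed (p = 0.232). A test against 1.5-fold gave 1089, 127 and 2310, as its stricter null requires. With a mean FPKM of at least 2 there were 240 lncRNA genes and 5313 genes and loci, and with no filter 13731, as fewer or more genes and loci were tested. No list passed with an estimated correlation, a count of 0 against 16. The share of the 10 most abundant genes, 0.569 points higher in tumours and never past the test, was -1.05 with 50 genes and -1.08 with protein-coding genes, and ranged from -1.45 to 2.20 without single pairs. In the UCSC-named table TG turned to a share of 0.260 points higher and a log2 change of 9.51, because it was listed at 0 in 11 noncancerous libraries. Among results that never passed, ACADVL turned to -0.0737 with sum scaling and CD74 to -0.0312 with quantile and -0.131 with sum scaling; without single pairs CD74 ranged from -0.121 to 0.275, below 0 also at -0.0572 and -0.105. Camera's direction turned for the class II list without replicate 5 (median -0.204, highest 0.260) and for the known lncRNA list without replicate 11 (median 0.122, lowest -0.312). The cause was not tested. The B and plasma cell call was also lost with fry (adjusted p = 0.125), a pseudocount of 0.01, quantile normalization, the stricter filter, the UCSC-named table and without replicates 2, 3, 4, 6 and 8 (adjusted p = 0.092 to 0.143), and the smooth muscle call in the UCSC-named table and without replicate 11. Myeloid markers passed as higher with no filter and without replicates 1 and 3. Of 136 named genes and loci, 95 kept direction and side of the threshold in every alternative run. Depth is known only relative to other libraries, so genes near 0 FPKM cannot be called absent.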

Other observations

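Counts in other classes of RNA follow, without a test of each class or another scaling. Of 200 snoRNA genes tested, 1 rose and 11 fell, with a median log2 change of -0.40, and of 121 immunoglobulin and T cell receptor segments none rose and 13 fell. Of 1651 pseudogenes, 95 rose and 155 fell, and of 116 snRNA genes 2 rose and 1 fell. Among lncRNA classes, 60 of 960 antisense genes rose and 198 fell, and 69 of 806 long intergenic genes rose and 141 fell. Of 329 sense intronic genes, 19 rose and 39 fell.

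Changes of loci without a symbol went with those of the nearest tested gene with a symbol on the same strand more than with those of other genes. Genes below the FPKM filter were not considered, so the distances below are to tested genes. Across 4110 loci within 10 kb of such a gene, Spearman's rho between the changes of locus and gene was 0.718, and 90.5% of 1285 changed loci had the sign of that gene. The correlation was 0.528 and the share 77.2% at 10 to 100 kb, and 0.340 and 76.2% across 2980 loci more than 100 kb away. In a test added after these values were seen, genes shuffled among the loci of each class in 1000 shuffles gave the same sign in at most 54.6%, 55.5% and 57.9%. These correlations are across loci from the same libraries, which are not independent replicates, so the shuffles overstate their precision.

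The tests of follicular cell share, of scaling and of stromal cells below were chosen after the values they measure had been seen; the tests of blood, level, depth, unspliced RNA and swapped pairs were written before, and the values over pairs for level, unspliced RNA and the lncRNA lean were added after. No swap of tumour and noncancerous within pairs came near the counts of changed genes: 1 of 100 swaps, the real one, reached 5526 GENCODE genes, with at most 1 gene in any other. The same held for the 602 lncRNA genes (1 of 100, at most 0). It also held for the 8958 genes and loci (1 of 100, at most 6). These values argue against no difference at all between tumour and noncancerous tissue. They do not show how many of the called genes are chance calls, which the adjusted p threshold allows. Real differences also add to the residual spread of swapped fits, which lowers the counts of the other swaps. Splits that ignored the pairs gave at most 1, 1 and 2, but their fits kept case as a block. They parted only 2 to 10 of the pairs, against 12 in the real grouping. Their low counts were partly built in and add no support. For the number of lists camera called, 16, chance cannot be excluded, as 5 of 100 swaps gave as many, the others reached up to 17, and their median was 10 lists.

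That count speaks of camera's preset correlation of 0.01 and not of each list. The correlations estimated within the 16 lists called ran from 0.0325 (skeletal muscle) to 0.890 (red cell genes). They reached 0.969 in the mitochondrially encoded mRNAs, which camera did not call. The exact swap test per list, chosen after the count over swaps was seen, passed 15 of the 16. The thyroid hormone synthesis and differentiation list was lower than all genes by a log2 difference of -1.76 ± 0.89 (SD, n = 12; adjusted p = 0.0024) in 12 of 12 pairs, and the papillary thyroid carcinoma markers were higher by 3.71 ± 1.15 (SD, n = 12; adjusted p = 0.0024) in 12 of 12. The B and plasma cell markers did not pass (adjusted p = 0.167).

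The fall of thyroid hormone synthesis and differentiation genes could reflect a lower share of follicular cells in the tumour samples. If tumour cells are counted as follicular, that would raise the markers of the other cell types. But 89 of these had a mean log2 change of -0.79 ± 0.75 (SD, n = 12 pairs; exact permutation p = 0.0054), which argues against it as the whole cause. The myeloid list among them was not lower (median 0.40). The test cannot see normal follicular cells replaced by tumour cells. Scaling between libraries is also argued against, since the list's median was -1.41 with quantile normalization. A change within the tumour cells remains open, as a hypothesis found on these data that was not itself tested.

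The fall of immediate early genes may follow the amount of blood in the samples. Over the 12 pairs, the changes of the immediate early and red cell lists had a Spearman's rho of 0.39 (permutation p = 0.209) and a Pearson's r of 0.284 (p = 0.373; 0.373 without the 2 most extreme pairs), which decides nothing. Fewer stromal and T cells could also carry it: the list changed by -0.42 ± 1.31 log2 relative to 57 of their markers (SD, n = 12; exact permutation p = 0.282), with a larger fall than the markers in 10 of 12 pairs. These signs lean against that explanation, but the test leaves it undecided. The explanations cannot be told apart here, and time between removal and freezing, which the labels do not give, was not tested.

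The lean of lncRNA genes towards lower values held over donors, with a median -0.20 ± 0.22 relative to protein-coding genes (SD, n = 12 pairs; exact permutation p = 0.0068), lower in 10 of 12. Lower depth is argued against, since in the 9 pairs with the deeper tumour library it was still -0.20 ± 0.24 (SD, n = 9; exact permutation p = 0.0195). Level stays open: the lncRNA median of -0.23 lay below the lowest 2.5% of 10000 protein-coding sets matched on mean FPKM (bound -0.14, median -0.11, difference -0.12), but that test counts genes as replicates, and over pairs the difference was -0.06 ± 0.24 (SD, n = 12; exact permutation p = 0.379). Less unspliced RNA stays open too, since sense intronic genes lay 0.15 above long intergenic ones over genes (permutation p = 0.0114) but 0.07 ± 0.37 over pairs (SD, n = 12; exact permutation p = 0.513) and 0.06 ± 0.37 with levels matched (p = 0.601). Scaling was left open as well, because quantile normalization brought the share of higher calls to 45.7% of 549.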
